A study of Mus musculus with 8 samples.

How the data were processed

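RNA from the mouse Sertoli cell line TTE3 was measured on 8 one-colour Affymetrix Mouse Expression 430A arrays, 2 at each of 4 times of exposure to 0.2 mM BPA (0, 3, 6 and 12 h). The groups and the array numbers within a time come from the sample titles. The deposited values are 1 intensity per probe set and array on a linear scale, all above 0, made by the authors. The software and the summary algorithm behind these signals are not given in the sources used here. From the values, each array had been scaled by the authors to the same mean: leaving out the top and bottom 2% of probe sets, the mean signal was between 500.16 and 500.18 on every array. Such a scaling holds the trimmed mean of the linear signals constant, so a general rise or fall of RNA would not be seen, and the balance of small rises and falls depends on it. It does not set log2 changes to 0: their median over all genes tested was 0.061, 0.072 and 0.058 at 3, 6 and 12 h. Scanner files and detection calls were not used here, so no probe set could be called present or absent, and low signals were handled by an offset and a filter. The ratio of 3' to 5' signal of the Gapdh control probe sets was between 0.713 and 0.82 on the 8 arrays and that of the actin control probe sets between 1.11 and 1.19, so RNA integrity by this measure was similar in all groups.

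Of 22690 probe sets, 64 controls were left out, 20380 had exactly 1 gene symbol in the platform annotation, 691 had several and 1555 had none. Symbols of 20351 probe sets were updated through their Entrez identifiers to the mouse RefSeq gene table of assembly GRCm38.p6, used for names alone; 29 kept the annotated symbol. Genes without a probe set of their own were not analysed here. Each of 12393 genes was represented by its probe set with the highest mean log2 signal. Probe sets of other parts of a transcript can differ, and the mean over all probe sets of a named gene was computed as an alternative. Probe sets whose ID ends in _s_at or _x_at can bind several transcripts; Gstm1, Clcn5, Taf1d, Xbp1, Hspa1b, Mt1, Tiparp, Mvd, Lss, Mcl1, Rps18, Rps2, Nop56, Psme4, Itga5, Clu and Wt1 were read by such probe sets and are uncertain to that degree.

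Signals were used as deposited and changed to log2(signal + 7.9), the offset being the 10th percentile of all values. Genes with a mean log2 signal above the 30th percentile were kept, which left 8675 and removed 3718. A linear model with 1 mean per time was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which gave 4 residual degrees of freedom and 9.00 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and genes with an adjusted p under 0.05 were called. Errors of log2 changes are standard errors from this model, and errors of signals are SD of 2 arrays. On simulated data with the signals of the 8675 genes for the 12 h comparison, 10 runs with 200 changed genes each, 79.8% of 2-fold and 95.5% of 4-fold changes were found, and 7.05% of calls were false. That false share is above the nominal 0.05. The simulated noise was independent between genes, and far more genes (3331) were called at 12 h in the data, so these rates need not carry over.

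Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists and 3 times together (93 tests); 27 list tests were called. With a correlation estimated from the arrays 5 were called: the ATF4 and CHOP list at 3, 6 and 12 h and the immediate early list at 3 and 6 h. Camera compares a list with all other genes, so a list can be called with few called members, and its direction can differ from the sign of the list's median. The lists held 792 entries, 712 of them on the array. Lists were compared between times with camera on the contrasts of the times, adjusted over these comparisons.

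The model, the lists, the alternatives and the rule for named genes were set before the data were examined, and so was the choice of the replicate numbers as an alternative block; the exceptions are named where they appear. The rule named, for each time against 0 h, the 10 genes that rose most and the 10 that fell most among called genes with a mean log2 signal above the median of the tested genes and with both treated arrays beyond both 0 h arrays. It also named up to 4 called members of each list at the time with the largest shift of the list, and 32 genes whatever their result; predicted genes were to be passed over, which happened 0 times. A few further list members (the exceptions within a list, such as Slc38a2, Xpot, Dusp1, Zmat3, Sesn2, Vldlr, Srebf1 and Ddit4) were chosen after their values were seen. Alternatives were quantile normalization, scaling to the same median, an offset of 1.975 or 31.6, no filter or one at the 50th percentile, eBayes without the trend, a fit of only the 2 groups compared, the replicate number as a block, all probe sets, a 2-fold minimum, an estimated correlation for lists, and leaving out each array in turn. Comparisons against the shared 0 h arrays were set against 100 simulations of unchanged groups. A separate 0 h array for each of 2 comparisons was also used, which was chosen after the data were seen.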

Results

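Gene expression was measured in TTE3, a mouse Sertoli cell line immortalized with a temperature-sensitive large T antigen of simian virus 40. Sertoli cells are the somatic cells of the testis that support germ cell development. The cells were exposed to 0.2 mM bisphenol A (BPA), a monomer of polycarbonate plastics and epoxy resins with weak estrogenic activity, for 0, 3, 6 or 12 h. Each time had 2 Affymetrix arrays, 8 in all, with 22690 probe sets each, and the number of arrays limits the precision of every value. The study asked which genes respond to BPA in Sertoli cells. The comparisons were each time against 0 h and the later times against each other. The labels do not say whether the 2 arrays of a time came from separate cultures, so the p-values measure the spread between these samples, which may be technical. No array without BPA at 3, 6 or 12 h was analysed here, so every change below combines BPA with time in culture.

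Signals are the authors' probe set signals on a linear scale, given as mean ± SD of 2 arrays. Median signals per array ranged from 150.8 at 0 h to 170.1 at 3 h, and replicates correlated at 0.974 to 0.984 across genes on the log2 scale. The 6 h arrays correlated with each other at 0.974, no better than one of them did with a 3 h array (0.975). Changes are on the log2(signal + 7.9) scale, which understates changes of low genes. In all, 8675 genes were tested, and 3103 of them (35.8%) changed over the time course by the moderated F test.

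At 3 h the largest rises were in immediate early and stress genes. Fos, a subunit of the AP-1 transcription factor, rose by 3.80 ± 0.12 (log2, SE; n = 2 per time), from a signal of 173.8 ± 14.8 to 2518 ± 110. Egr1, an early growth response transcription factor, rose by 3.74 ± 0.15, and the stress-induced genes Gadd45g and Atf3 by 3.74 ± 0.12 and 3.60 ± 0.11. Chac1, an enzyme that degrades glutathione, rose by 3.39 ± 0.13. The falls were smaller: among the called genes above the median signal the glutathione transferase gene Gstm1 fell most, by 1.68 ± 0.13, from 2805 ± 430 to 864.4 ± 35.1 (adjusted p = 2.24e-06).

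Of the immediate early and AP-1 genes, 21 of 28 measured rose at 3 h and none fell (22 and 0 when adjusted over the list alone). The median was 1.68 (camera adjusted p = 1.81e-25; adjusted p = 0.0139 with an estimated correlation). Among them were Klf10 (3.23), Ier2 (3.08) and Zfp36 (3.06), which encodes an RNA-binding protein that speeds the decay of AU-rich transcripts. Myc rose by 1.91 ± 0.10 (adjusted p = 6.54e-08). Other large rises were those of Errfi1, an inhibitor of the EGF receptor (3.43), and Ifrd1 (2.86).

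Genes listed for the ATF4 and CHOP branch of the unfolded protein response, the arm that runs through translation of Atf4, were already up at 3 h. What raised them was not tested. Of 19 measured genes 15 rose and none fell (15 and 0 adjusted over the list alone). The median was 1.26 (camera adjusted p = 3.7e-21; adjusted p = 0.0139 with an estimated correlation). Atf4 rose by 2.04 ± 0.11, Ddit3, which encodes CHOP, by 2.41 ± 0.11, and the pseudokinase gene Trib3 by 1.67 ± 0.11. Asns, the asparagine synthetase gene, rose by 0.49 ± 0.11 (adjusted p = 0.0112), but this call was lost with arrays scaled to the same median (adjusted p = 0.0598) or without the intensity trend (0.0557). It was also lost without replicate 1 at 0 h (0.121) or at 3 h (0.102). Hspa5, which encodes the chaperone BiP, had a change of 0.05 ± 0.13 (adjusted p = 0.871).

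Genes of cholesterol and fatty acid synthesis rose together: 17 of 27 rose and none fell (18 and 0 adjusted over the list alone). The median was 0.53 (camera adjusted p = 1.11e-10; adjusted p = 0.11 with an estimated correlation). Of the p53 targets 8 of 19 rose and 1 fell (10 and 1 over the list alone). The median was 0.34 (camera adjusted p = 0.000147; adjusted p = 0.25 with an estimated correlation). Those that rose included Gadd45a (2.26 ± 0.12), Plk2, Plk3 and Mdm2, the gene of the ubiquitin ligase that degrades p53. The p53 list shares Gadd45a and Sesn2 with the ATF4 and CHOP list, so the lists are not independent. Zmat3 fell. Cdkn1a, the gene of the cell cycle inhibitor p21, rose by 0.48 ± 0.12 (adjusted p = 0.022). It did not pass with arrays scaled to the same median (adjusted p = 0.0812) or without the intensity trend (0.105), nor without replicate 1 at 0 h (0.217) or either 3 h array (0.0745 and 0.151). Of the inflammation and NF-kB targets 7 of 15 rose and none fell (8 and 0 over the list alone). The median was 0.48 (camera adjusted p = 0.000272; adjusted p = 0.16 with an estimated correlation).

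By the same measure, the genes that fell most at 3 h after Gstm1 were Akr1cl, an aldo-keto reductase gene (-1.48), Skp1, a subunit of SCF ubiquitin ligases (-1.42), and Trappc1, a subunit of a vesicle tethering complex (-1.38). They were followed by Mrpl18, a mitochondrial ribosomal protein gene (-1.20), and the membrane protein genes Cd9 (-1.11), Cd24a (-1.10) and Tm4sf1 (-1.06). Lgals9, a galectin gene, fell by 1.08, and Tnrc6a, a component of microRNA silencing, by 1.06. The call of Tnrc6a was lost without either 0 h array, without replicate 2 at 3 h or without the intensity trend (adjusted p = 0.116, 0.0784, 0.109 and 0.107), and the mean of all its probe sets was -0.62. Gstm1 was read by a probe set that can also bind related genes. Small falls were seen over the respiratory chain, where 3 of 27 genes fell and none rose (3 and 0 over the list alone), at a median of -0.13 (camera adjusted p = 0.00154; adjusted p = 0.386 with an estimated correlation). The same was seen over the proteasome, where 3 of 29 fell and none rose (3 and 0 over the list alone), at a median of -0.13 (camera adjusted p = 0.000983; adjusted p = 0.386 with an estimated correlation). The proteasome call was lost after quantile normalization (adjusted p = 0.102).

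In total 1048 genes changed at 3 h, 742 higher and 306 lower, of which 212 and 29 changed at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). With all arrays scaled to the same median the split was 463 higher and 646 lower, and the median change of all genes went from 0.06 to -0.07, so the balance of small rises and falls is set by the scaling. The count was 611 without the intensity trend. It fell to 454 and 488 without replicate 1 or 2 at 0 h, and to 499 and 546 without replicate 1 or 2 at 3 h.

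**Figure D1:**
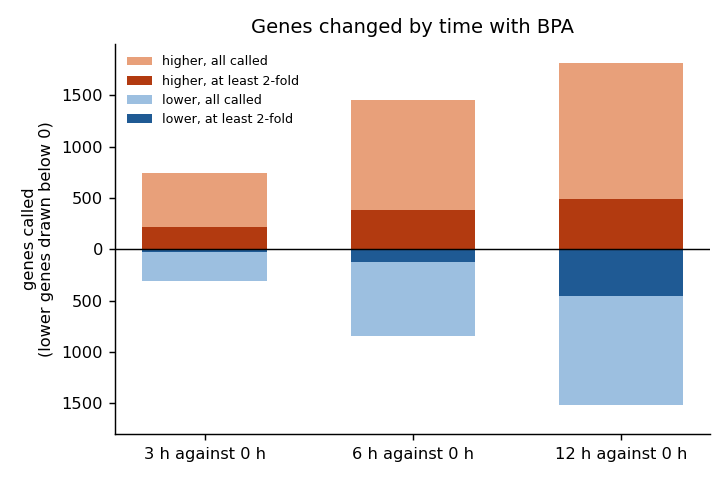
Number of genes called higher (above 0) or lower (below 0) at 3, 6 and 12 h against 0 h, with the genes that changed at least 2-fold in the darker shade. Called genes rose from 1048 at 3 h to 3331 at 12 h; lower genes went from 306 to 1521, and with arrays scaled to the same median the 3 h split was 463 higher and 646 lower.

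At 6 h several stress genes had climbed further and the sterol genes were at or near their highest. Chac1 rose by 4.05 ± 0.13 against 0 h, from 292.2 ± 17.7 to 5003 ± 878, and Trib3 by 3.12 ± 0.11. Fos was up by 3.94 ± 0.12 and Atf3 by 3.91 ± 0.11, but their steps from 3 to 6 h were not called. Gstm1 fell by 2.42 ± 0.13 to 514.5 ± 10.6. Akr1cl fell by 2.05 ± 0.14 and Cd24a fell by 1.98 ± 0.13.

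Of the ATF4 and CHOP genes 18 of 19 rose and none fell (18 and 0 adjusted over the list alone). The median was 1.92 (camera adjusted p = 6.59e-21; adjusted p = 0.0139 with an estimated correlation). Genes of amino acid synthesis and uptake and of tRNA charging followed: 15 of 27 rose and 2 fell (16 and 3 over the list alone). The median was 0.46 (camera adjusted p = 0.00313; adjusted p = 0.25 with an estimated correlation). The genes that fell were Slc38a2, an amino acid transporter gene, and Xpot, which encodes the tRNA exporter. Asns rose by 1.74 ± 0.11.

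Of the cholesterol and fatty acid genes 21 of 27 rose and none fell at 6 h (22 and 0 over the list alone). The median was 0.96 (camera adjusted p = 5.98e-13; adjusted p = 0.0983 with an estimated correlation). Mvd, Dhcr7 and Lss, enzymes of the mevalonate and sterol pathway, rose by 1.68 ± 0.14, 1.65 ± 0.16 and 1.53 ± 0.12, and Stard4, a sterol transfer protein gene, by 1.66 ± 0.12. The immediate early list was still up, with 18 of 28 higher and 1 lower (18 and 1 over the list alone). Their median was 1.03 (camera adjusted p = 8.71e-12; adjusted p = 0.0231 with an estimated correlation). The lower gene was the phosphatase gene Dusp1 (-0.34).

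Inflammation and NF-kB targets had 8 of 15 genes higher and none lower (8 and 0 over the list alone). The median was 1.10 (camera adjusted p = 9.38e-05; adjusted p = 0.141 with an estimated correlation). The chemokine gene Ccl7 rose by 3.46 ± 0.28, Ptgs2, which encodes cyclooxygenase 2, by 2.33 ± 0.18, Cxcl10 by 2.18 ± 0.24 and Tnfaip3, a negative regulator of NF-kB, by 1.83 ± 0.20. Of the p53 targets 10 of 19 rose and 4 fell (11 and 4 over the list alone). The median was 0.55 (camera adjusted p = 0.00993; adjusted p = 0.372 with an estimated correlation). This call was lost in the stricter filter (adjusted p = 0.134). Plk3 rose by 3.10 ± 0.20, Gadd45a by 3.01 ± 0.12, Plk2 by 2.02 ± 0.13 and Mdm2 by 1.67 ± 0.11.

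Other genes that rose strongly at 6 h were Gadd45g (3.81), Klf10 (3.51), Egr1 (3.31), Ifrd1 (3.12) and Siah2, a ubiquitin ligase gene (3.08; 2.09 as the mean of all its probe sets). Those that fell included Mrpl18 (-1.82), Skp1 (-1.80), Tm4sf1 (-1.66), Lgals9 (-1.61), Trappc1 (-1.59) and Jpt1 (-1.46). Clcn5, a chloride transporter gene, fell by 1.56 ± 0.38 (adjusted p = 0.00893). That call was lost without replicate 1 at 0 h, replicate 2 at 6 h or the intensity trend (limma adjusted p = 0.0735 without the trend). The fall of Clcn5 was 1.16 without replicate 1 at 0 h and 0.95 without replicate 2 at 6 h. The mean of all its probe sets was -0.92. The extracellular matrix list fell, with 9 of 28 lower and 1 higher (9 and 1 over the list alone). Their median was -0.22 (camera adjusted p = 0.000983; adjusted p = 0.25 with an estimated correlation). The respiratory chain had 5 of 27 lower and none higher (5 and 0 over the list alone). The median was -0.16 (camera adjusted p = 0.00276; adjusted p = 0.386 with an estimated correlation). Sdhc and Sdhd, the membrane subunits of succinate dehydrogenase, fell by 1.29 ± 0.14 and 1.17 ± 0.12. The proteasome had 4 of 29 lower and none higher (3 and 0 over the list alone). The median was -0.14 (camera adjusted p = 0.0107; adjusted p = 0.484 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.264) and without replicate 1 at 0 h (0.0658) or replicate 2 at 6 h (0.108).

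In total 2299 genes changed at 6 h, 1455 higher and 844 lower, of which 386 and 128 changed at least 2-fold. Scaled to the same median the split was 1054 higher and 1200 lower, with the median change of all genes going from 0.07 to -0.04, and the count fell to 1382 and 1378 without replicate 1 or 2 at 0 h.

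At 12 h, among the called genes above the median signal with both arrays beyond both 0 h arrays, Atf3, Trib3 and Chac1 were among those that rose most, and Gstm1, Thbs1 and Cxcl12 among those that fell most. Atf3 rose by 4.0 ± 0.11, from 408.6 ± 11.2 to 6671 ± 274, Trib3 by 3.88 ± 0.11, Chac1 by 3.86 ± 0.13 and Ddit3 by 3.47 ± 0.11, from 875.3 ± 83.0 to 9805 ± 973. Gstm1 fell by 2.80 ± 0.13 to 393.4 ± 25. Thbs1, which encodes the matrix protein thrombospondin 1, fell by 2.63 ± 0.11 from 3847 ± 110 to 616.8 ± 0.919. The chemokine gene Cxcl12 fell by 2.28 ± 0.11 from 4126 ± 122 to 842.2 ± 20.1.

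Of the ATF4 and CHOP genes 17 of 19 rose and none fell (17 and 0 adjusted over the list alone). The median was 2.44 (camera adjusted p = 1.88e-16; adjusted p = 0.0169 with an estimated correlation). Vegfa, the vascular growth factor gene, rose by 3.26 ± 0.16 and Gadd45a by 3.36 ± 0.12. Gadd45g, which is not in the list, rose by 3.56 ± 0.12. Atf4 itself stayed near its 3 h level, at 1.99 ± 0.11. Sesn2 and Vldlr had changes of -0.40 and -0.03 that did not pass the test. Of the amino acid and tRNA charging genes 21 of 27 rose and 2 fell (22 and 2 over the list alone). The median was 0.95 (camera adjusted p = 5.48e-07; adjusted p = 0.121 with an estimated correlation). Slc7a11, the cystine transporter gene, rose by 3.12 ± 0.37. Slc7a5 and Slc3a2, the subunits of a transporter of large neutral amino acids, rose by 2.67 ± 0.15 and 2.39 ± 0.12. Mthfd2, a mitochondrial folate enzyme gene, rose by 2.26 ± 0.15, and Asns by 2.68 ± 0.11.

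The chaperones of the endoplasmic reticulum (ER) did not move as a list: 3 of 23 rose and 4 fell (3 and 4 over the list alone). The median was -0.09 (camera adjusted p = 0.54). Hspa5 rose by 1.40 ± 0.13, from 7323 ± 93.6 to 19471 ± 3110, and Xbp1, a transcription factor of the unfolded protein response, by 0.91 ± 0.13. Hsp90b1, the gene of the chaperone GRP94, had a change of 0.02 ± 0.10 (adjusted p = 0.925). At 6 h Hspa5 (0.41, adjusted p = 0.0364) and Xbp1 (0.45, adjusted p = 0.0171) had risen too. These calls were lost with arrays scaled to the same median (adjusted p = 0.144 and 0.0617) and without the intensity trend (0.122 and 0.0725), and the mean of all probe sets of Xbp1 was 0.27. That of Hspa5 was also lost without any 1 of 5 arrays (0.0568 to 0.23), and that of Xbp1 without replicate 1 at 0 h or replicate 2 at 6 h (0.178 and 0.115). Calr, Pdia6 and Txndc5, a lectin chaperone gene and genes of protein disulfide isomerases, fell at 6 h by 0.69, 0.64 and 0.50, without Pdia6 passing the test at 12 h. The call of Pdia6 (-0.23 over all its probe sets) was lost without replicate 1 at 0 h, replicate 2 at 6 h or the intensity trend (adjusted p = 0.141, 0.0525 and 0.0568), and that of Txndc5 without replicate 1 at 0 h (adjusted p = 0.0537). At 3 h this list had 1 gene higher and 1 lower, with a median of -0.11 (camera adjusted p = 0.0586). It was called down at 3 h with arrays scaled to the same median, without a filter and without replicate 1 at 3 h (adjusted p = 0.0332, 0.0256 and 0.0385). The ER associated degradation and translocation list had 3 of 22 higher and 8 lower at 12 h (4 and 8 over the list alone; camera adjusted p = 0.224). In it Herpud1 rose by 2.44 ± 0.15 and Ube2g2 by 1.05 ± 0.12, while Sec61b, a translocon subunit, fell by 1.26 ± 0.11 and Spcs3, a signal peptidase subunit, by 0.81 ± 0.11.

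Of the extracellular matrix genes 17 of 28 fell at 12 h and none rose (19 and 0 over the list alone). The median was -0.57 (camera adjusted p = 5.71e-08; adjusted p = 0.11 with an estimated correlation). Besides Thbs1, the collagen gene Col1a1 fell by 1.54 ± 0.13, the membrane metalloprotease gene Mmp14 by 1.58 ± 0.15 and Mmp3 by 2.14 ± 0.60. The call of Mmp3 was lost without replicate 1 at 0 h or at 12 h, where its falls were 1.97 and 1.10. Peritubular and fibroblast markers, which share Col1a1, Col1a2 and Dcn with that list, had 3 of 7 lower and none higher at 12 h (3 and 0 over the list alone). The median was -0.37 (camera adjusted p = 0.0393; adjusted p = 0.25 with an estimated correlation; 0.0534 without a filter). At 6 h 3 were likewise lower, at a median of -0.42 (camera adjusted p = 0.0303; adjusted p = 0.25 with an estimated correlation; 0.0664 with arrays scaled to the same median). S100a4, a calcium-binding protein gene, fell by 2.58 ± 0.14 at 6 h, Col1a1 by 0.79 (0.28 over all its probe sets) and Dcn by 0.73. At 3 h the median of this list was 0.21 while camera placed it lower (adjusted p = 0.437). The actin and SRF target list had 7 of 19 lower and none higher at 12 h (6 and 0 over the list alone). The median was -0.12 (camera adjusted p = 0.0437; adjusted p = 0.459 with an estimated correlation). That call was lost without replicate 2 at 0 h (0.058) or at 12 h (0.0979) and in the stricter filter (0.0525). Ccn2, a matricellular growth factor gene, fell by 1.80 ± 0.13, the filamin gene Flna by 0.84, Itga5 by 0.66 and Tpm4 by 0.61. The call of Itga5 was lost without replicate 1 at 0 h or replicate 2 at 12 h (adjusted p = 0.0748 and 0.053).

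Cholesterol and fatty acid genes stayed up at 12 h, with 20 of 27 higher and 1 lower (20 and 1 over the list alone). Their median was 0.95 (camera adjusted p = 1.51e-08; adjusted p = 0.133 with an estimated correlation). The lower gene was the regulator Srebf1 (-0.47). Immediate early genes had 17 of 28 higher and 3 lower (17 and 3 over the list alone). The median was 0.92 (camera adjusted p = 7.24e-05; adjusted p = 0.0983 with an estimated correlation). Fos was still 2.84 ± 0.12 and Egr1 2.52 ± 0.15 above 0 h. Inflammation and NF-kB targets had 9 of 15 higher and none lower (9 and 0 over the list alone). The median was 0.80 (camera adjusted p = 0.000733; adjusted p = 0.182 with an estimated correlation). Cxcl10 rose by 4.26 ± 0.24 at 12 h, more than Atf3, with a mean signal below the median of the tested genes. Ribosome biogenesis and MYC targets had 12 of 27 higher and 1 lower (13 and 1 over the list alone). The median was 0.31 (camera adjusted p = 0.00308; adjusted p = 0.25 with an estimated correlation). Odc1, the ornithine decarboxylase gene, rose by 2.94 ± 0.11, the nucleolar protein genes Rrp12 and Nop56 by 1.03 ± 0.25 and 0.93 ± 0.12, and Nop16 fell by 1.12 ± 0.17. The call of Rrp12 was lost without replicate 2 at 0 h or at 12 h (adjusted p = 0.0735 and 0.0614), and the mean of all probe sets of Odc1 gave 2.03.

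Other large rises at 12 h were those of the phosphate transporter gene Slc20a1 (2.97), of Taf1d, a subunit of a polymerase I factor and a snoRNA host (3.10), and of the long noncoding RNA gene Pvt1 (2.96). The mean of all probe sets was 0.86 for Taf1d, 1.16 for Pvt1 and 2.28 for Slc20a1, so the probe sets of these genes differ. Brip1os (-2.24), Cd24a (-2.22), the growth arrest gene Gas1 (-2.21), the chromatin remodelling gene Arid2 (-2.15), Unc50 (-2.12), Akr1cl (-2.12) and Tm4sf1 (-2.11) were among the most lowered; over all probe sets Gas1 fell by 1.13 and Unc50 by 1.34.

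In total 3331 genes changed at 12 h, 1810 higher and 1521 lower, of which 491 and 453 changed at least 2-fold. Scaled to the same median the split was 1740 and 1534.

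**Figure D2:**
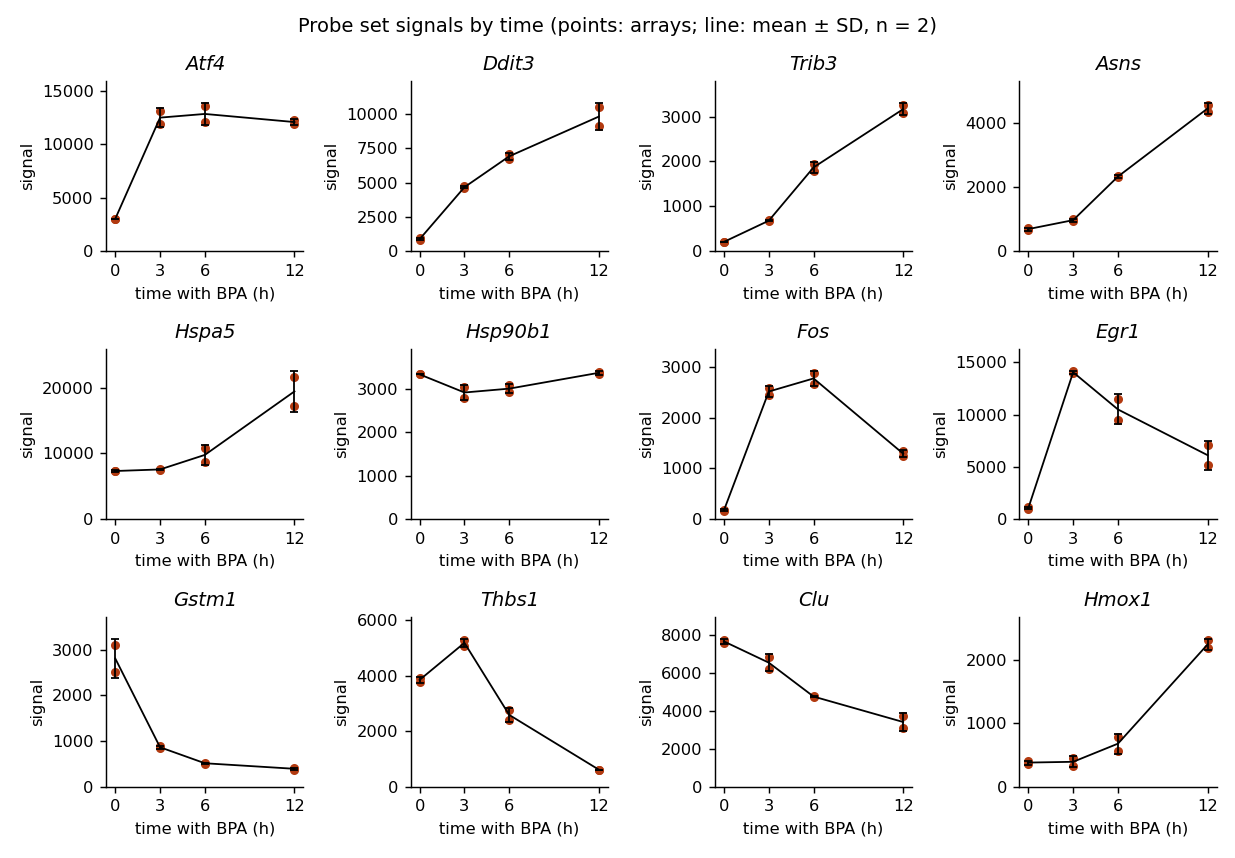
Probe set signal (linear scale, y axes from 0) of 12 genes against time with BPA in h; points are single arrays and the line joins means ± SD of 2 arrays. Ddit3, Trib3 and Asns climbed to 12 h, Atf4 was between 12087 and 12847 from 3 h on, Hspa5 reached 19471 at 12 h with Hsp90b1 at 3374, and Thbs1 went from 3847 to 5180 at 3 h and 617 at 12 h.

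Genes of oxidative and metal stress responded in part. Hmox1, the heme oxygenase gene, rose by 0.80 ± 0.18 at 6 h and 2.53 ± 0.18 at 12 h. The 6 h call was lost without replicate 2 at 0 h (adjusted p = 0.0538). NRF2 targets and glutathione genes went both ways. At 6 h 3 of 22 rose, among them Slc7a11 (2.11) and Osgin1 (1.42), and 6 fell, among them Gstm1 and Gsta3. Gsta3 fell by 2.02 (-0.76 over all its probe sets), but by only 0.91 without replicate 1 at 6 h. Its call was lost without that array, without either 0 h array or without the intensity trend (limma adjusted p = 0.0609 without the trend). The list was called down at 3 h, with 1 higher and 2 lower. Their median was -0.08 (camera adjusted p = 0.0449; adjusted p = 0.25 with an estimated correlation). It lost that call after quantile normalization (0.102), in the stricter filter (0.0942) and without any 1 of the 0, 3 or 12 h arrays (0.0511 to 0.0763). It was not called at 6 h (adjusted p = 0.0818, but 0.043 without a filter and 0.048 without replicate 2 at 6 h) or 12 h (7 higher, 6 lower, adjusted p = 0.731, with a median of -0.20 and a mean of 0.05). Of 6 metal response genes, the metallothionein genes Mt1 and Mt2 rose at 3 h (1.22 ± 0.13 and 2.20), at 6 h (1.44 and 2.48) and at 12 h (1.33 and 2.5; list at 6 h, adjusted p = 0.331). The probe set of Mt1 is among the brightest, at 8787 ± 725 before BPA, and the mean of all its probe sets gave 2.82, 2.62 and 2.14. Slc30a1, a zinc transporter gene, rose by 0.68 at 6 h, a call lost under both other scalings (adjusted p = 0.0947 and 0.092) and without any 1 of the 0, 3 or 6 h arrays (0.0519 to 0.214). Cytosolic heat shock genes had 7 of 20 higher and 1 lower at 12 h (camera adjusted p = 0.0919). Hsph1 (1.47), Hspa1a (1.10) and Hspa1b (0.88 ± 0.12) rose, and Cryab fell by 1.37.

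Xenobiotic and estrogen related genes did not move as lists. Of 6 measured targets and partners of the aryl hydrocarbon receptor, Tiparp (1.64) and Arnt (1.37; 0.79 over all its probe sets) rose at 12 h. Aldh3a1 (-1.65), Ephx1 (-1.40) and Ahr (-0.70 ± 0.15; -0.42 over all its probe sets) fell, and the list had an adjusted p of 0.571. Of 13 estrogen responsive genes, Nrip1 (0.87) and Xbp1 rose at 6 h, and Cxcl12 (-1.25) and Ccnd1 (-0.41) fell (list adjusted p = 0.989). Besides Xbp1, whose lost calls are given above, calls lost without 1 array here were those of Nrip1 (replicate 1 at 0 h or at 6 h, adjusted p = 0.0669 and 0.0567) and of Ccnd1 (either 0 h array, 0.199 and 0.142, or replicate 2 at 6 h, 0.259, or either 3 h array, 0.0622 and 0.0626). The call of Ccnd1 was also lost without the intensity trend (0.0931) and with only the groups compared (0.0529). The signals of Esr1 and Esr2, the estrogen receptor genes, lay between 5.4 and 43.9 and between 7.5 and 32.3 on all arrays, and those of Cyp1b1 between 12 and 52, under the filter, so these genes were not tested.

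Among cell cycle and cell death genes, the mitosis list had 6 of 28 lower and 1 higher at 12 h (6 and 1 over the list alone), with a median of -0.24, and missed the threshold (camera adjusted p = 0.0502; adjusted p = 0.25 with an estimated correlation). It was called without a filter (adjusted p = 0.0141), with the smaller offset (0.0495), with the replicate block (0.0444) and without replicate 1 at 12 h (0.0327). Ube2c fell by 0.77, Ccnb2 by 0.65, Ccna2 by 0.51 and Cdk1 by 0.50. The calls of Ccna2 and Cdk1 were lost without replicate 1 at 0 h (adjusted p = 0.052) and replicate 2 at 12 h (0.0566). In the DNA replication list 4 of 32 rose and 8 fell (camera adjusted p = 0.904). The cyclin E genes Ccne1 and Ccne2 fell by 1.32 ± 0.22 and 1.54 ± 0.31 and the thymidine kinase gene Tk1 by 1.42 ± 0.13, while Mcm10 rose by 1.05 (0.47 over all its probe sets). Ccnd1, the cyclin D1 gene, fell by 1.04 ± 0.14 at 12 h. Of 19 p53 targets 6 rose and 5 fell at 12 h (camera adjusted p = 0.449), and Cdkn1a had a change of 0.26 (adjusted p = 0.11; 0.87 as the mean of all its probe sets). Of 22 apoptosis regulators 4 rose and 3 fell at 6 h (camera adjusted p = 0.324). The inhibitor genes Birc2 and Birc3 rose by 1.13 and 1.01 (0.57 over all probe sets of Birc3), and Casp6 and the survival gene Mcl1 fell by 1.21 and 0.99. Bcl2 and Casp12 had changes at 12 h of 0.10 ± 0.47 and -0.25 ± 0.21 (adjusted p = 0.895 and 0.379).

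Sertoli cell genes moved apart. Clu, the gene of the secreted chaperone clusterin, fell by 0.69 ± 0.11 at 6 h and 1.17 ± 0.11 at 12 h, from 7650 ± 137 to 3409 ± 452. Inhbb, an inhibin and activin subunit gene, fell by 0.61 and 0.99, and Gata6 fell by 0.48 at 6 h. The 6 h call of Inhbb was lost without any 1 of the 4 arrays compared (adjusted p = 0.054 to 0.18), with a mean of all its probe sets of -0.36. That of Gata6 was lost without replicate 1 at 0 h (0.206), replicate 2 at 6 h (0.0628) or the intensity trend (0.0766). Gata4 rose by 0.45 at 6 h and 0.50 at 12 h (adjusted p = 0.0362 and 0.0154). Its 6 h call was lost under both other scalings, without replicate 2 at 0 h (0.353) and without either 6 h array (0.114 and 0.069). Its 12 h call was lost without replicate 2 at 0 h (0.206) or at 12 h (0.102), and both calls without the intensity trend (0.0942 and 0.0518). Sox9 rose at 3, 6 and 12 h by 1.83, 1.67 and 1.55 from a low signal of 43.5 ± 24.5, and over all its probe sets the 6 and 12 h changes were 0.53 and 0.45. Its 3 h call was lost without replicate 1 at 0 h or at 3 h (adjusted p = 0.0553 and 0.0535). Wt1 and Inhba had changes at 12 h of -0.67 and 0.90 (adjusted p = 0.0595 and 0.067; 0.0485 and 0.0333 with only the groups compared). As lists, the 17 Sertoli markers (3 higher, 3 lower at 6 h, adjusted p = 0.989) and the 12 junction genes (1 higher, 5 lower at 12 h, adjusted p = 0.133) did not pass. F11r, a tight junction gene, fell by 1.18 ± 0.12 at 12 h, Ctnnd1 by 0.91, Nectin2 by 0.77 and Nectin3 by 0.72 (adjusted p = 0.135 without replicate 2 at 0 h and 0.0602 without replicate 1 at 12 h). Apart from the peritubular markers, markers of other testis cells were not called as lists against 0 h. From 3 to 6 h the Leydig list was called down with 1 of 5 genes lower (camera adjusted p = 0.0175). With an estimated correlation that call was lost (camera adjusted p = 0.34). Of 5 Leydig genes Nr4a1 rose by 1.80 and Star fell by 0.57 at 6 h (list adjusted p = 0.695). Star lost its call without either 0 h array or without replicate 2 at 6 h (adjusted p = 0.119, 0.0534 and 0.0949), and the mean of all its probe sets was -0.22. Of 5 germ cell genes Kit fell by 1.27 at 12 h (list adjusted p = 0.286). Of 7 macrophage, leukocyte and endothelial genes none was called at any time (adjusted p = 0.913 at 12 h).

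The remaining lists were not called at any time. Of 21 hypoxia and glycolysis genes 4 rose and 4 fell at 6 h (camera adjusted p = 0.571). Vegfa (2.91), the ER oxidase gene Ero1a (1.48), Pfkfb3 (1.31) and the hexokinase gene Hk2 (1.24) rose. Of 27 lysosome and autophagy genes 7 rose and 3 fell at 12 h (camera adjusted p = 0.571), with Sqstm1 up by 1.32 ± 0.13, Atg12 by 0.98 and Atg3 by 0.93, and the kinase gene Ulk1 down by 1.36 ± 0.17. Of 16 interferon responsive genes Stat2 (1.18) and Irf1 (1.07) rose at 3 h and Ifi35 fell by 0.64 (list adjusted p = 0.763). Ifi35 lost its call without any 1 of the 4 arrays compared (adjusted p = 0.0767 to 0.23) and without the intensity trend (0.0903). Of 20 cytosolic ribosomal protein genes Rps18 and Rps2 rose at 12 h by 0.35 and 0.33 (none adjusted over the list alone; list adjusted p = 0.262), calls that were lost under both other scalings and without either 0 h array, either 3 h array, replicate 1 at 12 h or the intensity trend (0.122 and 0.117). The mean of all probe sets of Rps18 was -0.020, in the opposite direction.

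**Figure D3:**
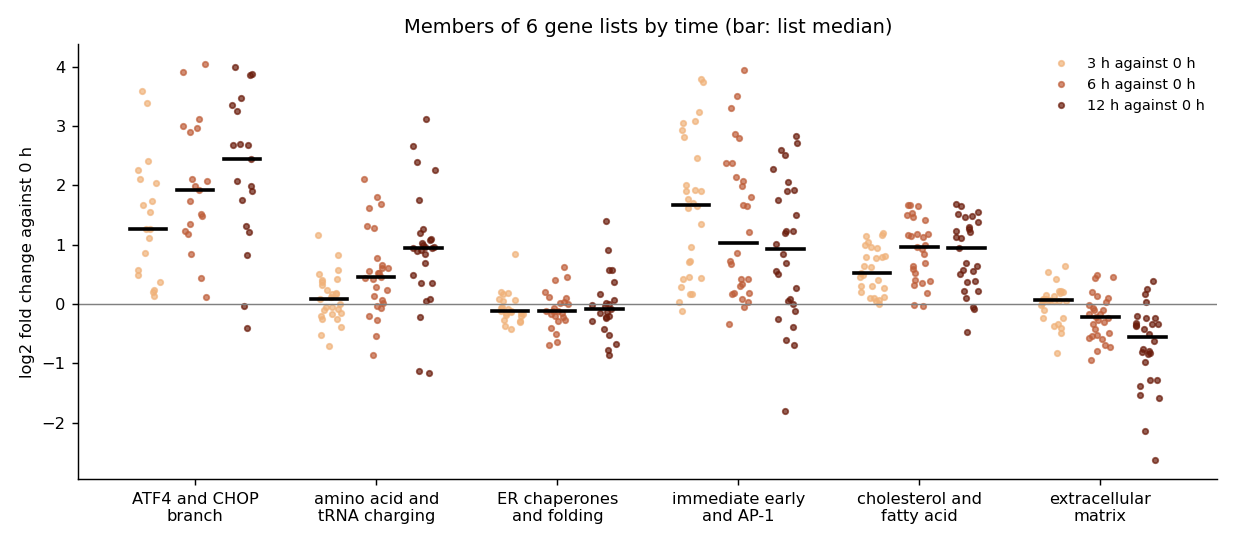
Log2 fold change against 0 h (y axis) of each measured member of 6 gene lists at 3, 6 and 12 h (colours), with the list median as a black bar. The ATF4 and CHOP median went from 1.26 to 2.44 and the extracellular matrix median from 0.06 to -0.57, while the ER chaperone median stayed between -0.12 and -0.09.

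Between the times, the ATF4 and CHOP list and the amino acid list shifted further up and the matrix list further down at the preset correlation, and none of these shifts was called with an estimated correlation. A minority of members was called from 3 to 6 h and from 6 to 12 h. From 3 to 12 h 13 of 19 ATF4 and CHOP genes were higher and 1 lower (13 and 2 over the list alone), 22 of 27 amino acid genes were higher and 2 lower (23 and 2), and 18 of 28 matrix genes were lower and none higher (19 and 0). From 3 to 6 h Trib3 rose by a further 1.45 ± 0.11, Asns by 1.26 ± 0.11 and Vegfa by 1.17 ± 0.16, while Ccn2 fell by 1.60 ± 0.13 and Thbs1 by 1.0 ± 0.11. From 6 to 12 h Cxcl10 rose by 2.08 ± 0.24, Hmox1 by 1.73 ± 0.18, Hspa5 by 0.99 ± 0.13 and Asns by 0.93 ± 0.11, and Thbs1 fell by 2.05 ± 0.11, Ccn2 by 1.84 ± 0.13, Fos by 1.10 ± 0.12 and Cxcl12 by 1.03 ± 0.11. From 3 to 6 h the median changes were 0.57 for the ATF4 and CHOP list, 0.37 for both the amino acid and the cholesterol list and -0.19 for the matrix list (camera adjusted p = 5.48e-13, 1.67e-09, 3.93e-11 and 1.86e-06; adjusted p = 0.0763, 0.0765, 0.0775 and 0.106 with an estimated correlation). The called members were 8 of 19, 6 of 27 and 3 of 27 higher and 2 of 28 lower, with none the other way (11, 14, 14 and 5 over the list alone). The immediate early list had a median of -0.15, with 7 of 28 lower and none higher (10 and 2 over the list alone; camera adjusted p = 5.71e-05; adjusted p = 0.0765 with an estimated correlation). From 6 to 12 h the amino acid list rose by a median of 0.47 and the matrix and immediate early lists had medians of -0.33 and -0.45 (camera adjusted p = 8.07e-10, 5.45e-09 and 8.58e-07; adjusted p = 0.0765, 0.0775 and 0.0763 with an estimated correlation). Of the amino acid genes 10 rose and 1 fell (15 and 1 over the list alone), and 8 matrix and 11 immediate early genes fell with none higher (12 lower and none higher, and 14 lower and 2 higher, over the list alone). The ATF4 and CHOP list had a median of 0.35, with 8 of 19 higher and 1 lower (10 and 2 over the list alone; camera adjusted p = 0.000159; adjusted p = 0.0793 with an estimated correlation). In it Ddit4 went from 1.98 at 6 h to 1.22 at 12 h. Chac1 went from 4.05 to 3.86, a step that was not called.

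From 3 to 12 h 1901 genes changed, 826 higher and 1075 lower. Scaled to the same median the split was 1411 higher and 770 lower, so the balance is set by the scaling, and the count fell to 1012 and 1080 without replicate 1 or 2 at 3 h and to 1110 without replicate 1 at 12 h. Fewer were called between adjacent times: 97 changed from 3 to 6 h, 49 higher and 48 lower, and 414 from 6 to 12 h, 80 higher and 334 lower. Scaled to the same median the 6 to 12 h split was 184 higher and 199 lower. Without the intensity trend the counts between adjacent times were 6 and 114, without a filter 56 and 274, with only the groups compared 62 and 162, and with the replicate block 226 and 703. The 3 to 6 h count fell to 61 without either 0 h array, to 30 and 39 without replicate 1 or 2 at 3 h and to 59 without replicate 1 at 6 h. The 6 to 12 h count fell to 251 and 250 without replicate 1 or 2 at 0 h and to 155 without replicate 1 at 12 h.

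The same genes tended to be called at successive times. Of the 742 genes higher at 3 h, 677 were higher at 6 h and 603 at 12 h, against 124 and 155 for independent lists. Of the 306 lower, 275 were lower at 6 h and 275 at 12 h, against 29.8 and 53.7. In all, 591 genes were higher and 263 lower at all 3 times. Unchanged groups simulated against the 0 h arrays shared 0.01 to 0.02 calls on average in 100 simulations. No gene changed at any time in them, so few calls could be shared. That count therefore does not measure what the shared 0 h arrays add to the overlap. Fold changes at 3 and 12 h correlated across genes at 0.67, against 0.50 in those simulations, with a covariance of 0.197 against 0.0286. With a separate 0 h array for each comparison the covariance was 0.172 and 0.169 for the 2 ways to assign them. Of 373 and 342 genes then higher at 3 h, 265 and 261 were higher at 12 h, against 57.8 and 51.1 for independent lists, and of 104 and 86 lower, 89 and 79 were lower at 12 h, against 12.9 and 10.3. A lone 0 h array is then assumed to vary like the other groups.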

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

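The tests of scaling and of time in culture for the ER pattern and the test of a handling pulse for the immediate early genes were chosen after the results were seen.

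Outside the genes tested, 1238 probe sets with no or several gene symbols passed the same filter, and 360 of them changed at 12 h, 164 higher and 196 lower, which drew attention because these probe sets enter no comparison. They have no name here and are not described further.

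Between 3 and 12 h, 10 lists differed by camera on that contrast at the preset correlation, and none of them did with an estimated correlation (adjusted p = 0.0763 to 0.413). The median change from 3 to 12 h was 1.07 for the ATF4 and CHOP list, 0.77 for amino acid and tRNA charging genes, 0.31 for cholesterol and fatty acid genes, 0.26 for ribosome biogenesis and 0.16 for cytosolic heat shock proteins. It was -0.68 for immediate early genes, -0.58 for peritubular and fibroblast markers, -0.50 for the extracellular matrix, -0.23 for mitosis and -0.18 for actin and SRF targets.

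A total of 12 genes were called in opposite directions at 3 and 12 h with the difference itself called. Adamts1, Amotl2, Bcar1, Ccn2, Dusp10, Dusp16, Efnb2, Ier3, Kmt2e, Thbs1 and Zfp52 were higher at 3 h and lower at 12 h, and Plagl1 was lower at 3 h and higher at 12 h. Apart from Ccn2 and Thbs1 these were singled out after their values were seen. Their 3 h calls differed in strength, from Ccn2 (1.64, limma adjusted p = 2.23e-06) to Ier3 (0.42, 0.042), with Efnb2 (0.50, 0.0406) and Thbs1 (0.43, 0.0197) also near the threshold. How these 3 h calls held under the alternatives is not given here. Adamts1 went from 665.8 ± 2.33 at 0 h to 1901 ± 55.1 at 3 h and 220.1 ± 57.3 at 12 h, and Ccn2 from 1778 ± 256 to 5549 ± 291 and 501.4 ± 25.1. Single genes that differed between times without a change of direction were not listed.

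The pattern most worth following is that the ATF4 and CHOP genes rose at 12 h (median 2.44) while the ER chaperones did not move as a list (median -0.09). A ceiling at the top of the signal range is argued against, since 100% of the 23 chaperone genes had a 0 h signal more than 4-fold below the brightest signal. That leaves room for a 4-fold rise. Flattening of bright signals below that maximum was not tested and stays open. The difference between the medians changed little with the processing. It was at least 2.35 after quantile normalization and with each other offset and filter, against 2.53 as analysed. This was a weak test of scaling: quantile normalization moved the median change of all genes at 12 h only from 0.058 to 0.034. Time in culture stays open, because 0 arrays without BPA after 0 h were analysed here. Hspa5 and Xbp1 rose within the chaperone list, so the pattern is a difference in extent over the list. No biological explanation was tested.

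Proteasome and respiratory chain genes together had a median of -0.13 at 3 h with few called members. Signal level alone seldom gave such a fall: 0.13% of 10000 random lists matched on signal had a median as low. Most of the random lists had medians between -0.088 and 0.044, below the median of all genes at 3 h (0.061). Part of the fall relative to all genes therefore goes with signal level. The random lists ignore correlation between genes, and both list calls were lost with an estimated correlation (camera adjusted p = 0.386 for each). Whether the rest exceeds a trend with signal level stays open. The authors' scaling stays open, because the median relative to all genes went from -0.19 as deposited to -0.087 after quantile normalization, between the bounds set for either answer.

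Immediate early genes were still up at 12 h, with a list median of 0.92, though the list call was lost with an estimated correlation (adjusted p = 0.0983). That median is the observation itself, and how long a pulse from handling at the start would last was not measured here, so handling stays open. Slower decay of short-lived transcripts may contribute. A list of 27 snoRNA host and splicing factor genes, many of which have transcripts open to nonsense-mediated decay, was drawn up after some genes were seen to rise. Among these were the snoRNA host Taf1d and the long noncoding RNA gene Pvt1. The list, whose prediction was written before its values were seen, left out the genes already seen to rise. It had a median of 0.487 at 12 h, with 14 of 23 measured higher and 3 lower (camera adjusted p = 0.000857 over the 3 times, and adjusted p = 0.109 with an estimated correlation). That median lay between the bounds set for either answer, so the prediction was not met. The list holds other transcripts than those of the immediate early genes, and no measurement of decay was used. Slower decay of the immediate early transcripts therefore cannot be told apart from induction here.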

How the results depend on the processing

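The alternative of leaving out probe sets that end in _s_at or _x_at, and all alternatives for the count from 3 to 12 h, were chosen after seeing the data; the first kept every count of called genes within 1.5 times. The counts of called genes at 12 h (2358 to 3543) and over the time course (2081 to 3477) stayed within 1.5 times without any single array; the others ranged from 454 to 1266 at 3 h, 1378 to 2332 at 6 h, 30 to 129 from 3 to 6 h, 155 to 428 from 6 to 12 h and 1012 to 2145 from 3 to 12 h. A lone array left at a time is then assumed to vary like the other groups. Requiring at least 2-fold left 241, 514 and 944 genes at 3, 6 and 12 h, 25, 70 and 354 from 3 to 6 h, from 6 to 12 h and from 3 to 12 h, and 1027 over the time course, by construction. Testing all probe sets gave 3457 at 6 h, 5293 at 12 h and 154 from 3 to 6 h, with more units tested. Without the intensity trend 611 genes were called at 3 h, 6 from 3 to 6 h and 114 from 6 to 12 h; without a filter 56 and 274 were called in these last comparisons, and with only the groups compared 62 and 162. The cause was not tested. With the replicate number as a replicate block 226 genes were called from 3 to 6 h and 703 from 6 to 12 h. The other counts were higher too, within 1.5 times. Same-numbered arrays deviated together by r = -0.011 to 0.122 across genes, which is weak. Neither the labels nor these values settle whether the numbers pair the samples. Rps18 at 12 h turned from 0.35 to -0.020 with the mean of all probe sets. Over the alternatives, list results were counted as kept in 1426 cases, lost a call in 40 and gained one in 10. For named genes these were 3305, 117 and 12, and 67 values moved with the mean of all probe sets. Results called in neither setting count as kept whatever their direction, and only 27 of 93 list tests were called as analysed. The tally therefore does not measure how robust the called results were. Without detection calls, the signal over background of low genes such as Esr1 and Sox9 is unknown.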

Other observations

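Among genes outside the named rule, chosen after their values were seen, transcripts of splicing regulators moved in both directions at 12 h. Genes of several such proteins rose: Tra2b by 1.35 ± 0.10, Luc7l by 1.23 ± 0.12, Clk3 by 1.03 ± 0.14 and Srsf10 by 0.92 ± 0.14. Srsf1 and Srsf5, genes of SR splicing factors, fell by 0.63 and 0.66. Noncoding hosts of snoRNAs rose, with Snhg5 at 1.74 ± 0.12 and Gas5 at 1.07 ± 0.17. Small rises at 3 h were already present in this list, with 12 of 23 genes higher and 1 lower and a median of 0.39 (camera adjusted p = 0.000172 over the 3 times; adjusted p = 0.109 with an estimated correlation).

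The genes that rose at 3 h and fell below the 0 h level by 12 h include Ccn2, Thbs1 and Amotl2, which are known targets of the YAP and TEAD transcription regulators. As a hypothesis, YAP and TEAD targets may turn down between 3 and 12 h. The prediction, written before the values of the list were seen, was that other targets would have a median change from 3 to 12 h below -0.5 and be called down. Of 20 such genes, with those already seen left out, 9 were measured; their median change was -0.96, with 7 lower and none higher (camera adjusted p = 0.000102 over the 4 comparisons made; adjusted p = 0.0524 with an estimated correlation, which misses the threshold). Lats2 fell by 1.76 and Ankrd1 by 1.88 from 3 to 12 h. Against 0 h the list had a median of -0.32 at 12 h, with 5 of 9 lower and none higher. Its camera adjusted p was 0.00686, and 0.0833 with an estimated correlation. Ankrd1 (-0.27) and F3 (0.007) were not called at 12 h against 0 h (limma adjusted p = 0.181 and 0.988). In these genes the fall was thus a return towards the 0 h level and not a fall below it. The list was not called up at 3 h, with a median of 0.05 (camera adjusted p = 0.541; adjusted p = 0.57 with an estimated correlation). Ankrd1 (1.62) and F3 (1.01) were higher then, so the values go with the fall and not with an early rise of the whole list. Time in culture and cell density, which were not measured here, stay open as sources.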
